A study of Mus musculus with 9 samples.

How the data were processed

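Bulk RNA sequencing was done on brain tissue of 9 APP/PS1 mice, a transgenic model of Alzheimer's disease amyloid pathology. The labels divide the animals into 3 groups of 3, exposed to stress, kept in a standard environment (control) or kept in an enriched environment. The treatment field of the labels reads standard rearing for all 9 animals, so the groups were taken from the group field, which matches the titles. Replicates were numbered in accession order within a group and pair no animals across groups. Each title carries a separate animal code, so the replicates were treated as separate animals. The code begins with C for all 3 stress animals, with D for all 3 enriched animals, and with C for control replicate 1 and D for control replicates 2 and 3. What the letter stands for is not given in the sources used here. Per the series' design text, the animals were perfused, and the brain stem together with the front part of the brain went into RNA extraction, so each library mixes several brain regions.

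Per the labels' protocols, messenger RNA was bound to oligo(dT) beads, fragmented and copied with random hexamers, and the amplified libraries were circularised and sequenced as DNA nanoballs. No unique molecular identifiers and no strand marking are described there. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the mouse build GRCm38.p6, without saying which tool did which step. The deposited table holds, for each coding RefSeq transcript, an estimated count that need not be whole, with 56.5% of the values not whole. It also holds the TPM that the authors computed (scaled by transcript length and library size) and an FPKM. The estimated counts were used in the main tests and the deposited TPM in 1 alternative, while the 9 FPKM columns were not used.

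The table has 65535 transcript rows, which together with its header line makes 65536 lines. The deposited TPM of a library sums to between 956737 and 960729 over these rows, so between 3.93% and 4.33% of each library's TPM belongs to transcripts not analysed here. Transcripts were summed to 18450 genes by gene identifier. Symbols and coordinates came from the RefSeq annotation of GRCm38.p6, the build the submitters' processing notes name, and 18398 identifiers matched. Of the 21896 protein-coding genes of that annotation, 3613 had no row. Every annotated coding transcript was present for 64.9% of the genes in the table and for 66.7% of the genes tested. A gene's value is therefore the sum over the transcripts with a row, and a change of isoform between present and absent transcripts would appear as a change of the gene. RSEM shares reads between similar transcripts by estimation, so members of gene families such as the MHC and haemoglobin genes are less certain than other genes. Without strand, reads from overlapping antisense genes cannot be told apart.

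Total estimated counts per library ranged from 15851833 to 17213008, and 16564 to 16801 genes had at least 1 read. At this depth 1 CPM (a count scaled by library size) corresponds to between 15.9 and 16.8 reads after TMM scaling. The precision given by n = 3 covers the spread between animals, and dissection is part of that spread. The 10 most abundant genes took 2.77% to 3.53% of a library. Libraries were compared for duplicates by a chi-square test of their counts over tested genes with at least 10 reads in a pair. The chi-square per gene was 9.43 or more for every pair within a group and 7.63 or more for every pair between groups. Both lie far above the value of about 1 that sampling noise gives, so all 9 libraries were kept as separate samples.

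Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which kept 14694 genes, and libraries were scaled by TMM factors between 0.964 and 1.025. All 9 libraries entered 1 fit of edgeR's quasi-likelihood test (robust), with 6 residual degrees of freedom, and the 3 groups were compared in pairs. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic of that test. CPM values use the TMM-scaled library sizes. In R 4.3.3, of 40 gene lists fixed in advance, the 37 with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The 37 lists were adjusted together within a comparison. Of the 532 different genes in the lists, 498 had a row. The 13 genes of the mitochondrial genome had none, and the lists of B and plasma cells and of sex-linked genes had fewer than 3 tested members, so these 3 lists were not tested. Single values per library, such as sums of T cell gene reads, were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3.

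The groups, the tests, the gene lists, the panel and the rule for named genes were fixed before the data were examined. The rule named, for each comparison, the genes past the threshold. Where fewer than 10 passed, it named the 5 higher and the 5 lower genes with the smallest p, as not passing. It also named a panel of 20 genes of T cells, microglia, astrocytes, amyloid, neuronal activity and the stress hormone axis. Not every gene the rule and the panel take is reported here. Other genes named in the text belong to the fixed lists or are said to have been chosen after their values were seen. Of the panel, Cd8a, Cd3e and Cxcr6 did not pass the count filter.

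The alternatives were DESeq2 size factors and upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, and limma on log2(TPM + 1). Further alternatives were no count filter, a mean CPM of at least 1, each pair of groups fitted alone, each library left out in turn, and a test against a fold change of 1.2. Covariates tried were the letter of the animal code, 1 surrogate variable (sva 3.50.0) and the first principal component of the region lists. Alternatives added after seeing the data are named in the closing section. For a check of length, the longest protein-coding transcript of each gene in GENCODE release M21 (GRCm38) was used, which was found for 98.2% of the genes tested. Before use, the test was run on simulated counts for the 14694 genes of the comparison of stress with control, drawn with these libraries' means, sizes and dispersions. Of 50 genes changed at each size, it recovered 18% at 1.5-fold, 62% at 2-fold, 88% at 3-fold and 92% at 4-fold, and 7% of its calls were unchanged genes. The simulated genes were drawn independently, without differences shared across a library, so these shares need not hold for the real libraries.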

Results

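Gene expression was measured by RNA sequencing in brain tissue from 9 APP/PS1 mice, which carry human transgenes that lead to amyloid plaques. Per the series' design text, the tissue was the brain stem and the front part of the brain. There were 3 mice exposed to stress, 3 in a standard environment (control) and 3 in an enriched environment. The series title relates stress, disease progression and CD8+ T cells. The comparisons thus ask how stress and an enriched environment relate to gene expression in the brain and whether T cell transcripts differ. Libraries held 15851833 to 17213008 estimated counts, and 14694 genes had enough counts to be tested. Over these genes, Pearson's correlation of log2 CPM between libraries ranged from 0.968 to 0.984 within groups (9 pairs) and from 0.955 to 0.988 between groups (27 pairs), a correlation across genes, which are not independent replicates.

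Regional and border-tissue transcripts varied widely between animals of the same group. Ttr (transthyretin, gene 22139, chromosome 18, 20664209 to 20674326 on GRCm38.p6), the most abundant transcript of the choroid plexus, was at 3120, 2940 and 3570 CPM in the controls. It was at 330, 1430 and 1390 CPM in stress replicates 1 to 3, and at 24, 2020 and 11 CPM in enriched replicates 1 to 3. The mean log2 CPM of 17 brain stem genes, which include Hox genes and markers of serotonin and noradrenaline neurons, spanned 3.35 over the controls, 3.14 over the stress libraries and 2.36 over the enriched libraries. Replicate 3 was the lowest library of each group for this list, at -2.22 in control, -2.22 in stress and -2.37 in enriched, relative to the control mean. Transcripts of the cerebellum, which the design text does not name, were abundant in all 3 groups, with a mean log2 CPM of 8.11 ± 0.45 in stress, 8.28 ± 0.22 in control and 8.17 ± 0.19 in enriched mice (10 genes). Cbln3, a gene of cerebellar granule cells, was at 670 ± 222, 723 ± 137 and 700 ± 109 CPM in the same order (SD, n = 3). Tph2, which makes serotonin in the brain, was at 56.3 CPM in stress replicate 1 and at 9.65 CPM or less in the other 8 libraries. Omp, the olfactory marker protein of olfactory sensory neurons, was at 67.3 and 50.3 CPM in enriched replicates 1 and 3 and at 4.06 CPM or less in the other 7 libraries (Tph2 and Omp were chosen after their values were seen). The first 3 principal components held 33.9%, 20.3% and 11.6% of the variance, and control replicates 1 and 2 lay at 45.9 and 34.3 on the first, with the other 7 libraries between -34.4 and 12.9.

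**Figure D1:**
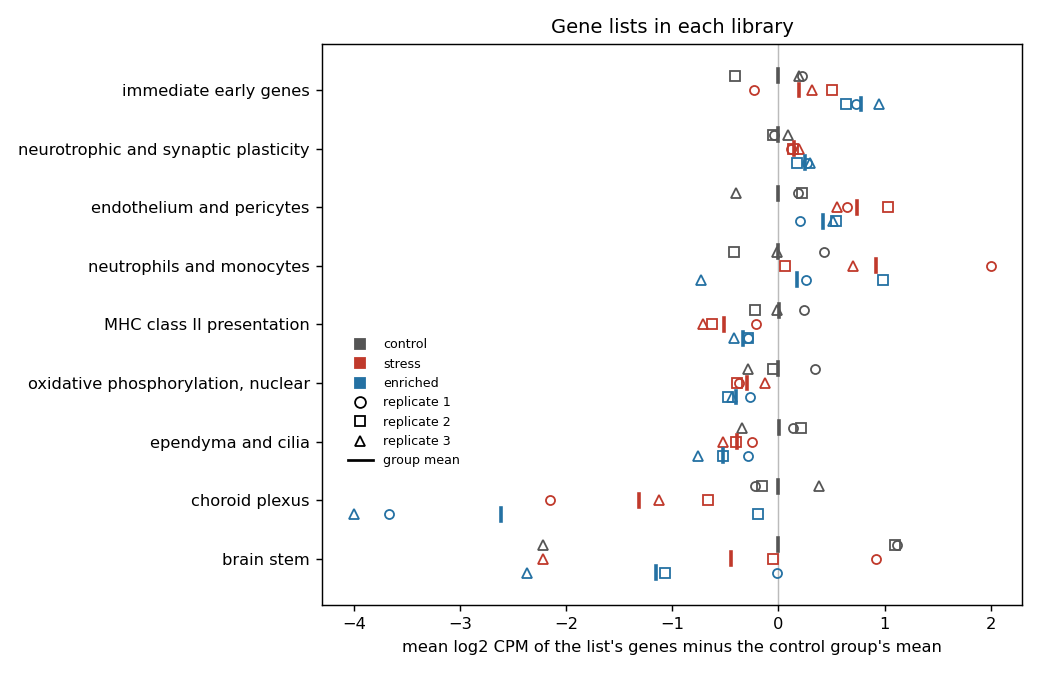
Mean log2 CPM of the genes of 9 fixed lists in each library, relative to the mean of the control libraries; symbols are single animals, colours are groups and vertical bars are group means. Choroid plexus genes spanned 3.81 over the enriched libraries and brain stem genes spanned 3.35 over the controls, while immediate early genes lay between 0.64 and 0.95 in all 3 enriched libraries.

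The first comparison was stress against control. Genes of endothelium and pericytes, the cells of brain capillaries, were higher in stress, with a mean log2 CPM of 4.67 ± 0.25 against 3.93 ± 0.35 (SD, n = 3 each). All 12 members had a log2 fold change above 0, among them Pecam1, an endothelial adhesion molecule (14.2 ± 7.11 against 5.44 ± 0.996 CPM), and Flt1, a VEGF receptor (45.2 ± 34.8 against 16.8 ± 2.91 CPM, SD, n = 3). Genes of MHC class II antigen presentation were lower, at 2.29 ± 0.27 against 2.81 ± 0.23, with all 7 members below 0. Cd74, the invariant chain, was at 15.7 ± 3.08 against 23.5 ± 3.61 CPM, and H2-Aa at 6.53 ± 2.41 against 11.4 ± 2.90 CPM (SD, n = 3). Choroid plexus genes were lower in stress by a log2 difference of -1.31, with all 11 members below 0.

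Of the 37 lists, 6 passed limma's camera test with a preset correlation. Adjusted p was 1.42e-04 for nuclear genes of oxidative phosphorylation (lower, 15 of 16 members), 1.44e-04 for endothelium and pericytes and 9.90e-04 for MHC class II. It was 0.00188 for ependyma and cilia (lower, 10 of 12), 0.00247 for neutrophils and monocytes (higher, 11 of 11) and 0.00249 for choroid plexus. With an estimated correlation none of the 6 held (adjusted p = 0.802 with an estimated correlation for each), and 1 list of the 37 was under an unadjusted p of 0.05. By fry, which asks whether a list's genes move on balance in one direction, the smallest adjusted p was 0.438, and 2 lists were under an unadjusted p of 0.05. Two-sided exact permutation tests of the list means gave p = 0.1 for endothelium and for choroid plexus, the smallest value that 3 against 3 allows, and p = 0.2 for the other 4 lists. Leaving out 1 library ended 4 of the 6 calls. For neutrophils the mean log2 fold change was 1.15 with all 9 libraries, 0.38 without stress replicate 1 (adjusted p by camera 0.126) and 1.21 without control replicate 3 (0.0573). For choroid plexus it was -1.21 with all 9, -1.25 without stress replicate 3 (0.0503) and -0.99 without control replicate 3 (0.133). For endothelium it was 0.85 with all 9 and 0.74 without control replicate 3 (0.0589), and for ependyma -0.46 with all 9 and -0.41 without stress replicate 3 (0.0558). With the length trend removed the oxidative phosphorylation and ependymal lists did not pass. Choroid plexus did not pass with the first region component or the first 2 as covariates, and with 2 its mean log2 fold change was 0.082.

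Members of these lists differed in how far single animals set the group value. Ngp, a neutrophil granule protein, was at 50.5, 11.6 and 20.2 CPM in the stress libraries against 9.77, 8.82 and 8.41 CPM in controls, so stress replicate 1 held the highest level. For Flt1 the stress values were 27.6, 85.2 and 22.7 CPM, with the highest in replicate 2. Cox4i1 and Uqcrq, subunits of complexes IV and III, were at 565 ± 69.2 against 753 ± 194 CPM and at 121 ± 26.3 against 179 ± 75.0 CPM (SD, n = 3), and control replicate 1 held the highest value of both (949 and 262 CPM). Foxj1, a regulator of motile cilia, was at 11.8 ± 3.57 CPM in stress and 20.3 ± 4.83 CPM in control (SD, n = 3). Adjusted over the list alone, 6 of 12 endothelial and pericyte genes and 5 of 7 MHC class II genes were called, and 1 immediate early gene. For the other lists, the count adjusted over the list alone was 0. The count over all genes tested was 0 for every list.

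No single gene passed in this comparison by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0 of 14694, smallest adjusted p = 0.187). At an unadjusted p under 0.05 there were 1172 genes (617 higher, 555 lower), DESeq2 called 7 and limma-voom called 0 (smallest adjusted p = 0.0521, with 5269 genes at an unadjusted p under 0.05). With the letter of the animal code as a covariate, edgeR called 3 genes and 3593 were under an unadjusted p of 0.05. The letter varies only among the controls, so that fit in effect set the stress libraries against control replicate 1 alone. Independent genes with no difference would give 735, but the 9 other splits of the same 6 libraries gave 94 to 4829, with 3 of them above the real count. Leaving out 1 library gave 725, 393 and 3086 genes without stress replicates 1, 2 and 3, and 470, 697 and 3555 without control replicates 1, 2 and 3. The 3 stress and 3 control values did not overlap for 9.8% of genes, against 10% by chance. The gene with the smallest p was Samd9l (gene 209086, chromosome 6, 3372257 to 3399571), an interferon-inducible antiviral gene, at 6.32 ± 0.892 CPM in stress and 2.17 ± 0.313 CPM in control (SD, n = 3). Its log2 fold change was 1.54 ± 0.19 (SE), and 1 of its 2 annotated coding transcripts had a row. Among higher genes that did not pass, Slc10a7 (log2 fold change 1.28 ± 0.25), Dyrk1b (0.66 ± 0.14), Gm14305 (1.02 ± 0.22) and Fyb (0.88 ± 0.19, SE) followed, each with adjusted p = 0.546 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among lower genes that did not pass were Pcolce, an enhancer of procollagen processing (-0.76 ± 0.15), the growth factor binding protein Igfbp2 (-0.85 ± 0.17), LOC115489330 (-1.05 ± 0.22) and Ldoc1 (-0.74 ± 0.16, SE), at the same adjusted p. DESeq2 placed Samd9l, Slc10a7, Dyrk1b, Igfbp2, Pcolce, LOC115489330 and Col24a1 past its threshold (Col24a1 was named after its values were seen).

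The second comparison was enriched environment against control. Immediate early genes, which neurons switch on within minutes of activity, were higher in the enriched group, with a mean log2 CPM of 4.89 ± 0.16 against 4.12 ± 0.35 (SD, n = 3 each), and 17 of 18 members lay above 0. Fosb was at 14.4 ± 3.28 against 5.92 ± 1.26 CPM, Egr2 at 6.32 ± 2.28 against 1.51 ± 0.472 CPM, Nr4a1 at 71.0 ± 7.70 against 36.7 ± 14.2 CPM and Fosl2 at 26.5 ± 6.70 against 10.9 ± 3.98 CPM (SD, n = 3). For 9 of the 18 genes, all 3 enriched values lay above all 3 control values, while Ier2 was lower in all 3 enriched animals (log2 fold change -0.40 ± 0.21, SE). Olfactory bulb genes moved with this list, at 5.69 ± 0.45 against 4.68 ± 1.11 (SD, n = 3) with 7 of 8 members above 0, without passing (adjusted p = 0.102 by camera). Relative to the control mean, the olfactory bulb list was at 0.44, -1.27 and 0.82 in control replicates 1 to 3. It was at 1.42, 0.54 and 1.09 in enriched replicates 1 to 3, so control replicate 2 carried much of the difference. Among the enriched libraries, those with the olfactory transcript Omp, replicates 1 and 3, had the higher Fosb, Fosl2, Egr2, Nr4a1, Arc and Npas4. Replicate 1 had the lowest Egr1 and Nr4a3, however, and replicate 3 the lowest Fos. The mean of the immediate early list was 0.73, 0.64 and 0.95 in enriched replicates 1 to 3, relative to the control mean. Nuclear genes of oxidative phosphorylation were lower, at 7.08 ± 0.11 against 7.48 ± 0.32, with all 16 members below 0, and Cox4i1 was at 501 ± 33.1 against 753 ± 194 CPM (SD, n = 3).

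**Figure D2:**
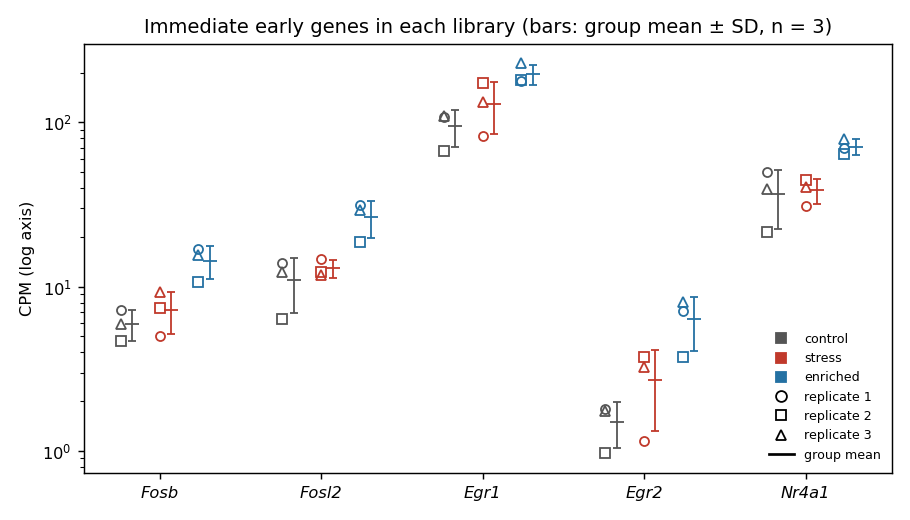
CPM on a log axis of 5 immediate early genes in each library, with the group mean and SD (n = 3) beside the points. Fosb was at 17, 10.7 and 15.6 CPM in the enriched libraries, above the 7.18, 4.65 and 5.93 CPM of the controls.

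Camera with a preset correlation called 7 of 37 lists. Adjusted p was 9.15e-06 for immediate early genes, 9.15e-06 for oxidative phosphorylation, 6.80e-05 for choroid plexus (lower, 11 of 11 members) and 0.00121 for ependyma and cilia (lower, 11 of 12). It was 0.0414 for endothelium and pericytes (higher, 11 of 12), 0.0419 for neurotrophic and synaptic plasticity genes (higher, 15 of 20) and 0.0419 for MHC class II (lower, 7 of 7). All 7 were lost with an estimated correlation (adjusted p = 0.964 with an estimated correlation for each), where 1 of the 37 lists was under an unadjusted p of 0.05. By fry the smallest adjusted p was 0.136, with 5 lists under an unadjusted p of 0.05. The two-sided exact permutation p of the list mean was 0.1, the smallest possible, for immediate early genes, plasticity genes and MHC class II, and 0.2 for the other 4. Leaving out 1 library ended 3 of the 7 calls, with the adjusted p by camera given here. MHC class II was at 0.0527, 0.0637, 0.104, 0.111 and 0.0898 without stress replicate 2, stress replicate 3, control replicate 1, control replicate 3 and enriched replicate 1. Plasticity genes were at 0.0528, 0.0818, 0.105 and 0.05 (before rounding above the threshold) without stress replicate 2, stress replicate 3, enriched replicate 1 and enriched replicate 3. Endothelium was at 0.051, 0.377, 0.102 and 0.0588 without stress replicate 3, control replicate 3, enriched replicate 2 and enriched replicate 3. In these settings the mean log2 fold change was -0.39 to -0.23 for MHC class II (-0.36 with all 9 libraries), 0.20 to 0.23 for plasticity genes (0.22) and 0.40 to 0.51 for endothelium (0.51). With the first region component as a covariate, 3 of the 7 calls stayed. Choroid plexus, ependyma, MHC class II and plasticity genes did not pass there.

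Within these lists, adjusted over the list alone, 9 immediate early genes, 12 oxidative phosphorylation genes, 2 ependymal genes and 1 plasticity gene were called, against 0 in each list over all genes tested. Across all 37 lists the calls adjusted over the list alone came to 27, with 1 each in the pituitary, T cell recruitment and oligodendrocyte precursor lists. Grin2b, an NMDA receptor subunit, was at 162 ± 20.5 against 85.6 ± 30.7 CPM, and Igf1, a growth factor, at 15 ± 3.65 against 6.12 ± 3.65 CPM (SD, n = 3), and all enriched values of both lay above the controls. Bdnf, a neurotrophin of the same list, was at 22 ± 5.06 against 19.4 ± 6.36 CPM. Choroid plexus genes split the enriched animals, since the list mean was -3.67 and -4.00 in replicates 1 and 3 and -0.19 in replicate 2, relative to control. Without replicates 1 and 3 the mean log2 fold change of the choroid plexus list was -0.25, a value that rests on replicate 2 as the 1 enriched library left. The brain stem list was at -0.01, -1.07 and -2.37 in enriched replicates 1 to 3 and did not pass (adjusted p = 0.0759 by camera). Controls also differed in transcript length composition, which moves with oxidative phosphorylation genes, whose longest coding transcript has a median of 750 bases. Genes with a longest transcript under 1 kb stood 0.53 above their mean over the 9 libraries (median log2) in control replicate 1 and -0.22 in enriched replicate 2. With the length trend removed, the oxidative phosphorylation list no longer passed and its mean log2 difference was -0.08 in both this comparison and that of stress with control.

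**Figure D3:**
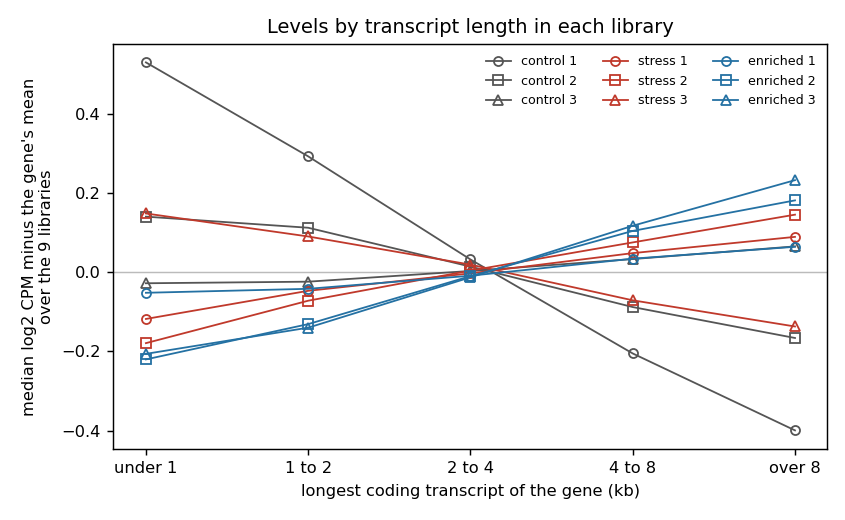
Median log2 CPM of genes in 5 classes of transcript length, relative to each gene's mean over the 9 libraries; each line is 1 library. Control replicate 1 runs from 0.53 for genes under 1 kb to -0.40 for genes over 8 kb, and enriched replicate 3 runs from -0.21 to 0.23.

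Single genes also did not pass here, with 0 of 14694 called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.180). There were 2994 genes at an unadjusted p under 0.05 (1459 higher, 1535 lower), and DESeq2 called 40 (27 higher, 13 lower). Independent genes with no difference would give 735, and the 9 other splits of these 6 libraries gave 79 to 3514, with 1 above the real count. The unadjusted count was 1024, 1554 and 5384 without control replicates 1, 2 and 3, 1647 and 1016 without enriched replicates 2 and 3, and 262 with the first region component as a covariate. With the letter of the animal code as a covariate it was 1005. The letter is D for all enriched animals and C for control replicate 1. That fit thus in effect set the enriched libraries against control replicates 2 and 3 alone. Limma-voom with sample weights called 4618, giving the 3 controls weights of 0.46, 2.84 and 0.41. Enriched and control values did not overlap for 26.1% of genes, against 10% by chance. Genes that move together can depart from that 10% without a group effect. The length slopes of the libraries did not overlap either, at -0.246, -0.087 and 0.028 in control and 0.037, 0.104 and 0.125 in enriched replicates 1 to 3. With the length trend removed, 1963 genes were under an unadjusted p of 0.05. How far length accounts for the 26.1% was not tested. Without control replicate 3 edgeR called 1586 genes, and without enriched replicate 2 it called 33. The higher genes with the smallest p, none of which passed, were Samd9l (6.35 ± 0.545 against 2.17 ± 0.313 CPM, log2 fold change 1.54 ± 0.19) and Slc10a7 (6.08 ± 0.284 against 2.44 ± 0.612 CPM, 1.32 ± 0.25, SE). With them came 3 genes of mucosal epithelium near the detection floor, Clca3a1 (77, 15 and 105 reads against 2, 1 and 3), Bpifa1 (24, 12 and 59 against 2, 1 and 2) and Reg3g (30, 15 and 13 against 2, 0 and 2). Among lower ones that did not pass were Pcolce (13.8 ± 2.48 against 26.9 ± 0.746 CPM), Rdh5, a retinol dehydrogenase (6.5 ± 1.86 against 15.1 ± 0.571 CPM), C1qtnf5 (17.6 ± 5.02 against 34.2 ± 4.02 CPM, SD, n = 3) and Calml4 (3, 1 and 2 reads against 20, 18 and 19). Apart from Samd9l, each of these genes had adjusted p = 0.236 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

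The third comparison set the stress and enriched groups against each other. Their animal codes begin with C for all stress and D for all enriched animals. Whatever the letter stands for thus differs along with the group in each value. Immediate early genes were lower in stress, with a mean log2 CPM of 4.31 ± 0.38 against 4.89 ± 0.16 (SD, n = 3 each), and 16 of 18 members lay below 0. Nr4a3, an activity-induced nuclear receptor (chromosome 4, 48045078 to 48086447), was at 10.5 ± 2.13 against 23.4 ± 4.05 CPM, and Fosb at 7.22 ± 2.10 against 14.4 ± 3.28 CPM (SD, n = 3). Nr4a1, Nr4a2, Fosl2 and Egr1 were also lower in all 3 stress animals, while Npas4 (12.3 ± 9.54 against 13.6 ± 4.32 CPM) and Btg2 (25.1 ± 6.25 against 25.4 ± 4.44 CPM, SD, n = 3) differed by less than their spread. Olfactory bulb genes were also lower in stress, at 5.06 ± 0.53 against 5.69 ± 0.45 (SD, n = 3) with 7 of 8 members below 0, without passing (adjusted p = 0.0927 by camera). Neutrophil and monocyte genes were higher in stress, with 11 of 11 members above 0 and Ngp at 27.4 ± 20.4 against 15.7 ± 8.85 CPM. Their mean log2 fold change of 0.87 was 0.10 without stress replicate 1. The choroid plexus list mean was 3.37 ± 0.76 in stress and 2.06 ± 2.11 in the enriched group (SD, n = 3), with 9 of 11 members above 0.

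Those were the 3 lists of 37 that camera called with a preset correlation, with adjusted p = 1.05e-09 for immediate early genes, 0.00249 for neutrophils and monocytes and 0.00911 for choroid plexus. Each had adjusted p = 0.677 with an estimated correlation, where 0 of 37 lists were under an unadjusted p of 0.05. By fry the smallest adjusted p was 0.773, and 1 list was under an unadjusted p of 0.05. A two-sided exact permutation test of the list mean gave p = 0.1 for immediate early genes, the smallest possible, 0.5 for neutrophils and 0.4 for choroid plexus. Adjusted over the list alone, 5 immediate early genes were called, and 0 genes of the other 36 lists, against 0 over all genes tested. Without 1 library, 2 of the 3 calls ended. The adjusted p by camera was 0.512 and 0.261 for neutrophils without stress replicate 1 and enriched replicate 3, and 0.27, 0.233 and 0.289 for choroid plexus without stress replicate 2, enriched replicate 1 and enriched replicate 3. In those last 3 settings the mean of edgeR's log2 fold changes of the choroid plexus genes lay below 0, at -0.10, -0.17 and -0.19, against 0.25 with all 9 libraries. Camera works on log2 CPM instead, where the list mean was higher in stress by 1.31 with all 9. Its direction stayed higher in stress in those 3 settings, so the measures did not share a direction there.

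Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14694 (smallest adjusted p = 0.999). At an unadjusted p under 0.05 there were 388 genes (183 higher, 205 lower), where the 9 other splits of these 6 libraries gave 105 to 790, and leaving out enriched replicate 1 or 3 gave 239 or 223, and DESeq2 and limma-voom called 0. Stress and enriched values did not overlap for 10.5% of genes, against 10% by chance. Higher in stress without passing were the dynein adaptor Bicd2 (79.5 ± 1.46 against 57.2 ± 6.28 CPM, log2 fold change 0.47 ± 0.10), Vwc2l (2.28 ± 0.242 against 0.367 ± 0.267 CPM), Cpne9 (53.8 ± 5.80 against 40.6 ± 1.19 CPM), Izumo4 and 2510002D24Rik. Among those lower without passing were Nr4a3 (log2 fold change -1.15 ± 0.24, SE), Trib1 (23.1 ± 2.87 against 34.1 ± 2.48 CPM, SD, n = 3) and the mucosal genes Bpifa1 and Reg3g, which had 4 reads or fewer in each stress library. Without enriched replicate 2, Omp and Stoml3, both transcripts of olfactory neurons and named after their values were seen, passed, and both were lower in stress.

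T cell transcripts were at the limit of detection in all 9 libraries. Cd8a, which encodes the CD8 alpha chain, had 3, 1 and 2 reads in the stress libraries, 4, 5 and 3 in controls and 2, 2 and 5 in the enriched libraries. The 5 genes Cd3d, Cd3e, Cd3g, Cd8a and Cd8b1 together had 7 to 15 reads in each library. Their sum was 0.754 ± 0.129 CPM in stress, 0.825 ± 0.0696 CPM in control and 0.567 ± 0.132 CPM in enriched mice (SD, n = 3), with two-sided exact permutation p = 0.6 for stress against control, 0.1 for enriched against control (the smallest that 3 against 3 allows, with all enriched sums below all controls) and 0.3 for stress against enriched. These 5 genes were grouped after their reads were seen. The 24 T cell and cytotoxic genes with a row summed to 6.35 ± 1.0, 6.80 ± 0.537 and 7.03 ± 1.05 CPM in the same order (SD, n = 3), with exact permutation p = 0.6, 0.7 and 0.5. Cxcr6, a chemokine receptor of resident T cells, had 2, 4 and 2 reads in stress, 5, 5 and 0 in control and 12, 3 and 13 in enriched mice. Its ligand Cxcl16 was at 2.22 ± 0.609, 3.38 ± 1.36 and 2.94 ± 0.622 CPM (SD, n = 3). Only 5 genes of the list, Cd4, Lck, Zap70, Ccl5 and Ctsw, had enough reads for the test, and the list did not pass in any comparison (adjusted p by camera 0.302, 0.881 and 0.269). With so few reads and 3 animals per group, these values show neither a difference in T cell content nor its absence.

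Among genes of plaque-associated microglia, Trem2, a lipid receptor of microglia, was at 26.6 ± 9.63 CPM in stress, 28.8 ± 5.48 in control and 29.5 ± 5.39 in enriched mice (SD, n = 3). Cst7 was at 11.1 ± 5.91, 9.60 ± 2.59 and 14.7 ± 6.21 CPM, and Clec7a at 5.11 ± 1.54, 3.32 ± 0.740 and 5.71 ± 1.93 CPM in the same order. For the whole list of 22 genes, 11 were above 0 in stress against control, 14 in enriched against control and 10 in stress against enriched, and the list did not pass by camera (adjusted p = 0.743, 0.573 and 0.343). The homeostatic marker Tmem119 was at 22.4 ± 3.0, 23.7 ± 2.50 and 23.8 ± 2.63 CPM. In astrocytes, Gfap was at 401 ± 72.5, 474 ± 51.5 and 413 ± 61.7 CPM and Serpina3n at 53.7 ± 9.22, 54.2 ± 19.6 and 43.3 ± 11.8 CPM (SD, n = 3). Complement, interferon response, MHC class I, T cell recruitment and reactive astrocyte lists did not pass in any of the 3 comparisons.

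No gene of the amyloid and stress hormone lists passed in any comparison by edgeR's quasi-likelihood test. App was at 2873 ± 113, 2718 ± 320 and 3039 ± 246 CPM in stress, control and enriched mice, and Apoe at 2363 ± 425, 2861 ± 456 and 2528 ± 428 CPM (SD, n = 3). Reads of the human transgenes would reach these mouse rows only where they align to the mouse sequence. The 19 genes of amyloid processing and clearance did not pass by camera (adjusted p = 0.479, 0.951 and 0.282). Fkbp5, a target of the glucocorticoid receptor, was at 22.6 ± 1.54 CPM in stress, 28.0 ± 3.26 in control and 29.2 ± 6.47 in enriched mice, with a log2 fold change of -0.31 ± 0.17 (SE) for stress against control. Nr3c1, that receptor, was at 91.5 ± 2.18, 81.4 ± 17.9 and 102 ± 15.4 CPM, and Crh, the corticotropin-releasing hormone, at 4.45 ± 1.51, 5.57 ± 2.46 and 6.59 ± 1.88 CPM (SD, n = 3). Pomc, the precursor of the hormone ACTH, was at 1.09, 0.862 and 51.3 CPM in stress replicates 1 to 3 and at 1.57, 1.21 and 0.847 CPM in controls (log2 fold change 3.87 ± 1.51, SE), so 1 library set its difference. Hsd11b1, which regenerates glucocorticoid, was lower in all 3 stress animals than in all controls (46.9 ± 3.50 against 60.4 ± 5.66 CPM), as was the receptor Crhr2 (1.51 ± 0.376 against 2.52 ± 0.242 CPM, SD, n = 3). Against the enriched animals, 0 of the 9 tested genes of the stress hormone axis were lower in all 3 stress animals. Of the same 9 genes, 2 were lower in all 3 enriched animals than in all controls. A shift particular to stress was therefore not shown. The 18 glucocorticoid response genes gave adjusted p by camera of 0.384, 0.878 and 0.329, and the 9 tested genes of the stress hormone axis 0.721, 0.855 and 0.315. None of the panel genes passed in any comparison by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For Fos, the values were 25.0 ± 11.4, 21.1 ± 2.11 and 36.8 ± 3.0 CPM in stress, control and enriched mice, and for Arc 87.2 ± 32.6, 83.4 ± 26.0 and 125 ± 23.4 CPM (SD, n = 3).

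The stress and enriched log2 differences from control shared their sign for most genes, with Samd9l, Slc10a7 and Pcolce among the smallest p in both. Both also moved with transcript length (Spearman correlation across 14432 genes, which are not independent replicates, 0.413 for stress and 0.53 for enriched), and control replicate 1 had the steepest slope, -0.246 in log2 CPM per doubling of length. Over 14694 genes, the log2 differences of stress from control and of enriched from control had a correlation of 0.778 and a covariance of 0.103, and 83.6% had the same sign. Both differences use the same 3 control libraries, and unchanged groups simulated against shared controls gave a mean correlation of 0.502 (0.470 to 0.540 in 50 simulations), a covariance of 0.038 and the same sign for 66.7% of genes. The covariance lay 0.064 above the simulated one. The simulation drew each gene independently and so lacked the library-wide differences in length and region of these data. Its range is therefore too narrow to judge the excess. Random relabelling of the 9 libraries gave a mean correlation of 0.463 and a highest value of 0.763, with 0 of 100 relabellings as high as the real labels, and the same sign for up to 84.4% of genes, with 1 of 100 as high. The relabelled covariance reached 0.098, with 0 of 100 as high. Part of the excess may come from the shared controls, since 3 controls cannot be divided into sets of 2. No overlap of calls could be computed, because edgeR called 0 genes in either comparison.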

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

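The tests chosen only after the result was seen were those on genes with every coding transcript in the table, without the 2 libraries with almost no Ttr, without the library of each group lowest in brain stem genes, with the first 2 region components as covariates, and with the length trend removed. Gene counts by edgeR's quasi-likelihood test were 0 in all 3 comparisons with other scaling factors, with no filter or a stricter one, with each pair of groups fitted alone, with 1 surrogate variable, with 1 or 2 region components, against a fold change of 1.2, with the length trend removed, on genes with every coding transcript and without the 2 libraries with almost no Ttr. Limma on log2(TPM + 1) also called 0. At an unadjusted p under 0.05 these settings gave 374 to 1315 genes for stress against control, 262 to 3208 for enriched against control and 109 to 583 for stress against enriched. The DESeq2 test called 7, 40 and 0 genes in that order, and limma-voom called 0, 4618 and 0. With 1 library left out, the unadjusted counts ran from 393 to 3555, from 1016 to 5384 and from 223 to 578, and stress against control stayed at 0 genes. Enriched against control ranged from 0 to 1586 genes (1586 without control replicate 3 and 33 without enriched replicate 2), and stress against enriched from 0 to 2 (Omp and Stoml3 without enriched replicate 2, named after their values were seen). The letter of the animal code as a covariate gave 3, 0 and 1 genes (Zfp965 and Paqr8 among the 3, named after their values were seen). At an unadjusted p under 0.05 it gave 3593, 1005 and 672 genes, against 1172, 2994 and 388 without it. Without the library of each group lowest in brain stem genes, the counts were 135 (110 higher, 25 lower), 68 (63 higher, 5 lower) and 0. That setting left out replicate 3 of each group. The libraries left had length slopes of -0.246 and -0.087 in control, 0.048 and 0.074 in stress and 0.037 and 0.104 in enriched. The sign of the slope thus divided the controls from both other groups there. Control replicate 3, also left out where 1586 genes were called, had a slope of 0.028. The cause of these shifts in gene counts was not tested. List calls by camera ranged over the left-out libraries from 5 to 13 for stress against control (12 without stress replicate 1, 13 without control replicate 1), against 6 with all 9. They ranged from 4 to 9 for enriched against control (4 without stress replicate 3), against 7, and from 1 to 14 for stress against enriched (14 without stress replicate 3, 1 without enriched replicate 3, and 5 without stress replicate 1, enriched replicate 1 or enriched replicate 2), against 3. An estimated correlation left 0, 0 and 0 lists, and fry gave 0, 0 and 0. Stress against enriched had 1 list with only genes with every coding transcript and 5 lists without the 2 libraries with almost no Ttr. Without the library of each group lowest in brain stem genes, stress against control had 3 lists, which held 2 of the 6 called with all 9 libraries. MHC class II, endothelium, neutrophils and choroid plexus did not pass there. In the same setting stress against enriched had 5 lists, which held 1 of the 3 called with all 9. Direction turned for choroid plexus with the first 2 region components, to 0.082 for stress against control, 0.129 for enriched against control and -0.047 for stress against enriched (mean log2 fold change), none past the threshold. Without the 2 libraries with almost no Ttr, which leaves enriched replicate 2 alone in its group and assumes that it varies like the other groups, choroid plexus for stress against enriched turned to -0.97, and camera's direction for neutrophils turned although their mean log2 fold change was 0.20. Immediate early genes passed camera in 16 of 16 settings with the preset correlation for enriched against control (0.47 to 0.86) and in 16 of 16 for stress against enriched (-0.70 to -0.36), but not with an estimated correlation (adjusted p = 0.964 and adjusted p = 0.677 with an estimated correlation). Oxidative phosphorylation passed in 15 of 16 settings in both comparisons with control. Of the other lists, MHC class II passed in 6, plasticity in 7, endothelium in 11 (values down to 0.09), choroid plexus in 12 and ependyma in 15 of 16 for enriched against control, choroid plexus in 8 and neutrophils in 9 of 16 for stress against enriched, and the other 5 lists of stress against control in 11 to 15 of 16. Over all lists called, 82 of 108, 82 of 126 and 33 of 54 values kept their side of the threshold, the estimated correlation and fry included. Of the values of named genes, 8 of 693, 39 of 691 and 0 of 691 came past it. The correlation of the stress and enriched changes was 0.729 to 0.863 with 1 control left out (0.863 without control replicate 3), against 0.778. Sex as a covariate was not run, since Xist had no row and Y-linked genes had at most 2 reads in any library, and the alternatives for normalized values were not run because counts were present. No paired analysis was possible because the replicate numbers were assigned here and pair no animals.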

Other observations

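The tests of uneven choroid plexus and of uneven olfactory bulb, and the single genes named in this part, were chosen only after the result was seen.

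Genes of homeostatic microglia leaned higher in the enriched group without passing, with 11 of 12 members above 0 against control and a mean log2 CPM of 5.12 ± 0.16 against 4.79 ± 0.22 (SD, n = 3; adjusted p = 0.0834 by camera and adjusted p = 0.964 with an estimated correlation). The purinergic receptor P2ry12 was at 28.9 ± 5.73 against 16.7 ± 7.18 CPM, and the transcription factor Sall1 at 67.1 ± 22.5 against 29.2 ± 15.1 CPM (SD, n = 3). Interferon response genes lay above 0 for 18 of 21 members in stress against control (adjusted p = 0.0718 by camera) and for 15 of 21 in enriched against control (adjusted p = 0.102). Ifi44 was at 1.06 ± 0.0909 CPM in stress, 0.932 ± 0.236 CPM in enriched and 0.423 ± 0.263 CPM in control mice (SD, n = 3). Bst2, of the same list, was lower in every stress and enriched library than in every control, at 6.60 ± 1.97, 7.05 ± 0.696 and 10.3 ± 2.24 CPM in stress, enriched and control mice (SD, n = 3). Among clock genes, Per2 was at 24.4 ± 4.27 CPM in stress, 27.8 ± 1.99 CPM in enriched and 19.6 ± 3.91 CPM in control mice, and the list did not pass (adjusted p by camera 0.334 for stress and 0.201 for enriched against control). Heat shock genes lay below 0 for 8 of 9 members in stress and 9 of 9 in enriched mice against control, also without passing (adjusted p by camera 0.165 and 0.261).

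Some transcripts of particular regions or cell types were high in only a few libraries. The olfactory neuron genes Omp, Stoml3 and S100a5 were at 67.3, 11.1 and 24.3 CPM in enriched replicate 1 and at 50.3, 10.5 and 18.4 CPM in enriched replicate 3, against 0.476, 0.416 and 0.0595 CPM in enriched replicate 2. The mean of the olfactory bulb list was also highest in enriched replicates 1 and 3, at 1.42 and 1.09 relative to the control mean. It was at 0.82 in control replicate 3, however, where Omp was at 0.424 CPM. Of the mucosal genes, Clca3a1 (77, 15 and 105 reads in enriched replicates 1 to 3) and Bpifa1 (24, 12 and 59) were highest in replicates 1 and 3. Reg3g (30, 15 and 13) was not. Which tissue carried Omp was not tested. The serotonin transporter Slc6a4 was at 34.5 CPM in stress replicate 1 and at 3.38 CPM or less in the other 8 libraries. Haemoglobin and other red cell genes spanned 2.51 in mean log2 CPM over the stress libraries, 0.98 over the controls and 1.02 over the enriched libraries. Calml4, Rdh5 and Pcolce were low in enriched replicate 2 as well (0.0595, 8.56 and 16.6 CPM), although Ttr was at 2020 CPM there, and each was lower in all 6 stress and enriched libraries than in all 3 controls.

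Immediate early genes were higher in the enriched than in the control group. Removing each library's trend with transcript length left the mean log2 difference at 0.77, a ratio of 1 to the value before (1 to 1.01 leaving out 1 library), which argues against transcript length bias between libraries. Adjusting for the first region component gave 0.47, a ratio of 0.61 that ran from 0.27 to 1.05 with 1 library left out, so uneven dissection of brain regions cannot be told apart from a group effect with 9 libraries. Adjusting for the mean of the olfactory bulb list gave 0.53, a ratio of 0.68 (0.58 to 0.97). Uneven amounts of olfactory bulb in the dissected pieces thus also stay open as part of the difference. Omp is not in that list, and tissue carrying Omp was not adjusted for. Activity of neurons under enriched housing may account for some or all of it, as a hypothesis found on the same libraries, while handling and the time of day at tissue collection are not given in the sources used here and were not tested.

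Nuclear genes of oxidative phosphorylation were lower in both the stress and the enriched group than in control. The list mean was 0.34, -0.05 and -0.29 in control replicates 1 to 3, relative to the control mean. It was -0.37, -0.39 and -0.13 in stress and -0.27, -0.48 and -0.44 in enriched replicates 1 to 3. Control replicate 1 thus raised the control mean, and control replicate 3 lay within the range of both other groups. Removing the length trend took the mean log2 difference from -0.40 to -0.08 for enriched (ratio 0.2, 0.15 to 0.23 leaving out 1 library) and from -0.30 to -0.08 for stress (ratio 0.25, 0.2 to 0.33), so transcript length bias between libraries may account for most of it. Adjusting for the first region component left a ratio of 0.97 for stress (0.65 to 1.27), which argues there against uneven dissection of the kind that component carries. Unevenness of regions that it does not carry was not tested, so dissection stays open for stress in that respect. For enriched the ratio was 0.96 but ran from 0.2 to 1.38, so dissection stays open. Where the length trend itself comes from was not tested, and an effect of stress or of the enriched environment stays open.

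Choroid plexus genes were lower in the enriched than in the control group. Their list mean spanned 3.81 over the enriched libraries, more than the group difference of 2.62, and 10 of 11 members were lower in replicates 1 and 3 than in replicate 2, as uneven amounts of choroid plexus in the dissected pieces would give. This split was seen before the range was tested, so it is no independent evidence for uneven dissection. Members with every coding transcript in the table had a median log2 fold change of -1.45, which argues against transcripts without a row. Uneven dissection and an effect of housing on the choroid plexus both stay open.

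With 3 libraries against 3 there are 10 splits of the 6 libraries, which cannot give a share under 0.05. For genes past the threshold, 10 of the 10 splits gave at least the real count in each comparison, since the real count was 0 by edgeR (1172, 2994 and 388 genes at an unadjusted p under 0.05; DESeq2 called 7, 40 and 0 and limma-voom 0, 4618 and 0). The highest other counts were 1315 for stress against control, 0 for enriched against control and 1 for stress against enriched, and at an unadjusted p under 0.05 they were 4829, 3514 and 790, each above the real labels. The split with 1315 genes set stress replicates 1 and 2 with control replicate 3 against the other 3 libraries. This points to a structure of the samples apart from stress. The first 3 had length slopes of 0.048, 0.074 and 0.028 in log2 CPM per doubling of length. Stress replicate 3 had -0.084, and control replicates 1 and 2 had -0.246 and -0.087. The split thus followed the sign of the length slope, though whether the length trend gave these calls was not tested. For lists, 9, 9 and 10 of the 10 splits gave as many calls as the real 6, 7 and 3, and the highest other counts were 14, 12 and 15.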
